A study of Rattus norvegicus with 16 samples.

How the data were processed

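Liver RNA of 16 male Sprague Dawley rats was hybridized to Affymetrix Rat Exon 1.0 ST arrays, 1 array per animal, in 4 groups of 4. The values are log2 signal intensities per transcript cluster, made by the authors with Affymetrix GCOS 1.4 and Expression Console 1.1, per the submitters' processing notes. The summarisation, the background correction and the probe set level are not given in the sources used here. That the scale is a base 2 logarithm was inferred from the range of the deposited values, 0.84 to 13.6. A log2 signal from an array can be compressed at both ends, so fold changes of very dim or very bright genes may come out too small. The values were used as deposited, with no further scaling. Fasting durations and times of sampling are not given in the sources used here.

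The table has 19418 rows, of which 533 with identifiers below the annotated range carry no gene name and were left out of the tests. Of the 18885 rows tested, 13327 carry 1 gene symbol, 620 carry several and 4938 carry none. The 13215 genes with a row of their own were represented by the row of highest mean signal. Symbols come from the probe table of the array and from RefSeq annotation of assembly GRCr8, which was used also for the lengths of genes (their span), known for 99.3% of these genes. The files name no genome build, and no coordinates are given.

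Groups were compared with limma 3.58.1 in R 4.3.3: 1 linear model with a mean per group over all 16 arrays, 5 contrasts, moderated statistics from eBayes, two-sided tests and Benjamini-Hochberg adjustment over all rows tested, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, over the 41 of 42 lists with at least 5 measured members. Of the 938 genes on the lists, 703 had a row of their own, and the others were not analysed here. The lists cover fuel metabolism, mitochondria, redox defence, hormone signalling, stress, proteolysis, growth and the clock, and 10 lists hold markers of cell types. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, for each comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes whose groups do not overlap, up to 4 called members per list, and a set of 30 key genes of which 26 had a row. The text names a part of them.

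The same steps were tested on simulated data. There 18885 rows were drawn independently around the real means with the moderated spreads of the fit, and 50 genes were changed by each of 4 known folds. Far fewer genes were changed than were called in P2 or P3 against fed, which makes the adjusted threshold stricter. The shares called may therefore be too low for these 2 comparisons. For P2 against fed, 28% of genes changed 1.5-fold, 82% of those changed 2-fold and 100% of those changed 4-fold were called, for P3 against fed 32%, 72% and 100%, and for P3r2 against fed 20%, 82% and 100%. Overlaps of calls between comparisons that share a group were set against independent lists of the same sizes, against 100 simulations in which the other 2 groups did not differ, and against splits of the shared arrays 2 against 2. Alternatives tried were quantile normalization, centring of each array on its median, trend and robust options of eBayes, array weights, a fit of the 2 groups alone, a filter on dim rows, a stricter threshold of 0.01, the mean of all rows of a gene, the replicate number as a block and each array left out in turn. The 3 arrays of narrow spread left out, the spread as a covariate, the trend with gene length taken out and the rows without gene names included were added after the data were seen. Figures were drawn with matplotlib 3.10.9.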

Results

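Gene expression was measured on exon arrays in the livers of 16 male rats, in 4 groups of 4: fed animals, animals fasted to phase 2 of fasting (P2), animals fasted to phase 3 (P3), and animals fasted to phase 3 and then re-fed for 2 days (P3r2). In phase 2 of a long fast, fat stores are the main fuel and body protein is spared, and in phase 3 protein breakdown rises. The comparisons ask how the liver's fuel and antioxidant genes differ between these states and how far re-feeding reverses the difference. Each array is 1 animal, and the number of arrays limits the precision of every value. The arrays correlated at 0.966 to 0.992 within groups and at 0.912 to 0.985 between groups. Of the variance, 39.1% lay on the first principal component and 20.6% on the second. Across the arrays, the median log2 signal lay between 4.34 and 4.46. By standard deviation, values spread least in fed 2, P2 4 and P3 3 (2.12, 2.14 and 2.18 log2 units). These arrays are called the 3 arrays of narrow spread below. They were picked by low array weights (0.39, 0.41 and 0.38), which fall when an array fits its group poorly. Their upper quartiles lay 1.56, 1.49 and 1.68 log2 units above the median, where P2 1 and P2 2 had 1.67 and 1.65. Spread also differed by group: the mean of this distance was 1.85 in fed, 1.65 in P2, 1.94 in P3 and 2.03 in P3r2. In the text, changes are log2 fold changes ± the standard error of the fit, with 4 arrays per group, and "called" stands for a limma adjusted p below 0.05 over 18885 rows.

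**Figure D1:**
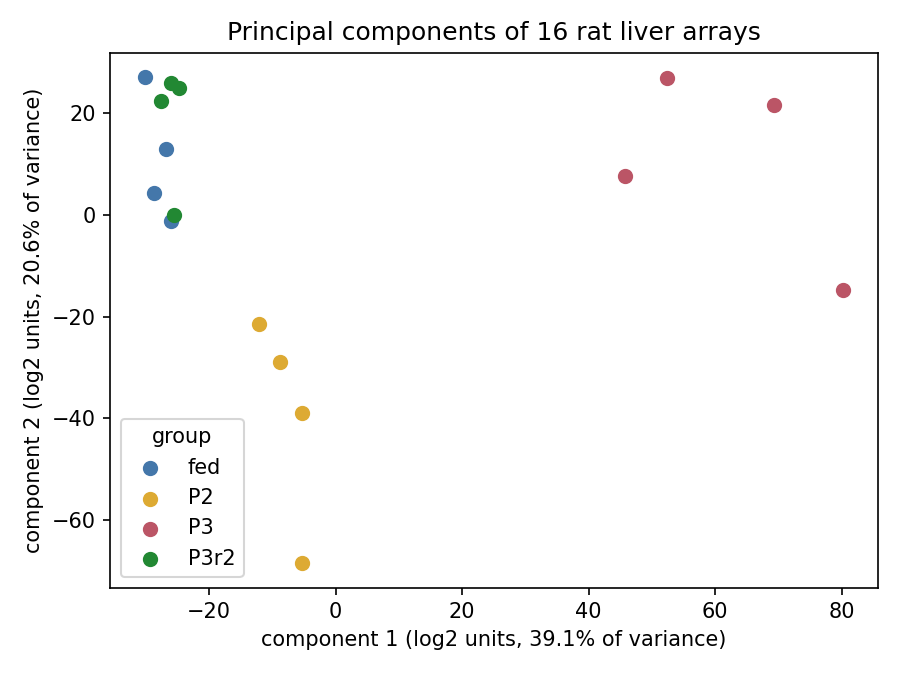
Principal components 1 and 2 of the log2 signals of all rows tested, in log2 units. Each point is 1 rat liver, coloured by group, and the percentages on the axes are shares of the variance. The fed and re-fed arrays lie next to each other, and the P2 and P3 arrays lie apart from them and from each other.

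At phase 2, the livers held far less mRNA of many enzymes that make fatty acids and cholesterol than fed livers. Scd (transcript cluster 7062917), the desaturase that makes oleate, fell by 7.49 ± 0.42 log2 units (adjusted p = 2.1e-07), and Elovl6, a fatty acid elongase, fell by 4.31 ± 0.28 (adjusted p = 5.8e-07). Igfbp1 (transcript cluster 7120834), a binding protein of insulin-like growth factors that insulin represses, rose by 3.13 ± 0.22 (adjusted p = 1.5e-06), as did Igfbp2 (2.60 ± 0.27). Ech1 (2.08 ± 0.23) and Decr1 (1.84 ± 0.27), which handle unsaturated fatty acids during their oxidation, rose, as did Serpina7 (2.91 ± 0.50), the thyroxine-binding globulin. The falls also took in Slc34a2 (-3.47 ± 0.46), a phosphate transporter, and Paqr9 (-3.32 ± 0.34), a membrane receptor of the progestin and adiponectin receptor family.

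Of the 18 measured members of the lipogenesis list, 14 fell (16 adjusted over the list alone; camera adjusted p = 1.8e-19, adjusted p = 0.072 with an estimated correlation). Among them were Pklr (-3.53 ± 0.33), the liver pyruvate kinase, Fads1 (-3.46 ± 0.34), the delta-5 desaturase, and Srebf1 (-2.13 ± 0.21), a transcription factor that drives the pathway. In the cholesterol list, 13 of 17 members fell (14 adjusted over the list alone; camera adjusted p = 3.2e-14, adjusted p = 0.086 with an estimated correlation). Examples were Sqle (-2.42 ± 0.27), Acat2 (-2.39 ± 0.28) and Dhcr7 (-2.24 ± 0.25), enzymes of sterol synthesis. The glycogen list fell with 3 of 7 members called (5 adjusted over the list alone; camera adjusted p = 0.0033, adjusted p = 0.58 with an estimated correlation). Among them were Pygl (-1.77 ± 0.24), glycogen phosphorylase, and Ppp1r3b (-1.58 ± 0.31), which brings protein phosphatase 1 to glycogen. Fatty acid oxidation genes did not move as a list (camera adjusted p = 0.17): 5 of 28 rose, among them Eci1 (1.73 ± 0.29), and 1 fell, Plin2 (-1.42 ± 0.22), a lipid droplet protein. Of the 5 measured ketogenesis genes, 3 fell, among them Bdh1 (-1.38 ± 0.19), which makes 3-hydroxybutyrate (camera adjusted p = 0.069 for the list). Cpt1a (0.54 ± 0.30), the entry enzyme of mitochondrial fatty acid oxidation, was not called.

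Many genes of the respiratory chain and some of antioxidant defence were higher at phase 2. In the oxidative phosphorylation list 27 of 42 members rose and 1 fell (31 rose and 2 fell adjusted over the list alone; camera adjusted p = 5.0e-13, adjusted p = 0.58 with an estimated correlation). Examples were Atp5mc2 (1.72 ± 0.30), Cox4i1 (1.57 ± 0.24) and Atp5me (1.36 ± 0.21). Among antioxidant enzymes, 15 of 34 rose and 1 fell (21 rose and 2 fell adjusted over the list alone; camera adjusted p = 3.6e-05, adjusted p = 0.88 with an estimated correlation). They included the peroxiredoxins Prdx4 (1.18 ± 0.26) and Prdx5 (1.11 ± 0.24), the glutaredoxin Glrx (1.09 ± 0.20) and the cytosolic superoxide dismutase Sod1 (0.60 ± 0.14). Gpx1 (0.56 ± 0.15), glutathione peroxidase 1, was also called, but its adjusted p was 0.076 without the 3 arrays of narrow spread and up to 0.086 with single arrays left out (P2 4). Cat (-0.38 ± 0.46), catalase, Hmox1 (0.52 ± 0.41), heme oxygenase 1, and Gsr (0.00 ± 0.17), glutathione reductase, were not called. The proteasome list rose, with 11 of 28 members up and 3 down (13 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.89 with an estimated correlation). Among them were Psma6 (1.59 ± 0.28) and Psmb1 (1.34 ± 0.24). Without fed 2 the adjusted p of this list was 0.078. Cell cycle genes fell in 7 of 26 cases (12 adjusted over the list alone; camera adjusted p = 3.6e-05, adjusted p = 0.58 with an estimated correlation). The list was led by Ccnd1 (-2.38 ± 0.26), cyclin D1, and Top2a (-1.43 ± 0.23), topoisomerase 2-alpha. Over the brighter rows alone the adjusted p of the cell cycle list was 0.098.

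The fold changes of this comparison also followed gene length. Across 8225 brighter rows with a known gene length, the Spearman correlation across genes of log2 fold change with length was -0.38, and genes are not independent replicates. With these rows in 5 groups of equal size by length, the shortest group had a median of 0.20 with 323 rows up and 71 down, and the longest group had -0.35 with 44 up and 367 down. With this trend taken out of each array over these rows, the median of the oxidative phosphorylation list was 0.68 (camera adjusted p = 4.5e-09), against 0.65 over all rows before. The antioxidant list had 0.54 (adjusted p = 3.3e-05) against 0.56, and the proteasome list 0.28 (adjusted p = 0.043) against 0.40. The medians before and after come from different sets of rows, so they do not show the effect of the correction alone. None of these 3 list calls held with an estimated correlation before the trend was taken out (adjusted p = 0.58, 0.88 and 0.89), and Gpx1 was no longer called with the trend taken out (adjusted p = 0.23).

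In all, 1158 rows were higher and 1242 lower in P2 than in fed livers, 250 and 406 of them by at least 2-fold. Of all rows tested, 19.2% had no overlap between the 4 values of 1 group and the 4 of the other, where chance gives 2.86%. Among the 2400 rows called 2104 had none, but rows were called on these same values. The counts of higher and lower rows leaned on single arrays. The higher count was 681 without fed 4, 731 without P2 2 and 608 without P2 4. The lower count was 755 without fed 1, 596 without fed 4, 790 without P2 2 and 592 without P2 4. Without fed 2 there were 885 higher and 1548 lower. With the spread of each array as a covariate the balance turned to 1060 higher and 769 lower. Of 41 lists tested, 9 were called, and with an estimated correlation camera called 0, against 2 lists at an unadjusted p below 0.05. Of the 35 splits of these 8 arrays into 4 and 4, 9 called as many lists, the real one included. The other splits that did so kept most arrays of a group together. They carry a part of the real difference and do not measure chance alone.

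At phase 3, the livers differed from fed livers in more genes and by larger steps. Car3 (transcript cluster 7206114), the muscle-type carbonic anhydrase that fat and liver also hold, fell by 7.94 ± 0.19 log2 units (adjusted p = 9.0e-13), and Cyp2c11, the male-specific steroid hydroxylase of rat liver, fell by 6.30 ± 0.50. Gadd45b (transcript cluster 7322066), a stress-induced regulator of growth arrest, rose by 6.12 ± 0.17 (adjusted p = 5.2e-12), Igfbp1 by 5.97 ± 0.22 and Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, by 5.10 ± 0.29. The largest changes also held Fst (4.71 ± 0.18), follistatin, which binds activins, Rdh16 (4.74 ± 0.19), a retinol dehydrogenase, Pptc7 (4.89 ± 0.18), a mitochondrial phosphatase, and Slc22a8 (-6.22 ± 0.34), an organic anion transporter.

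Lipogenesis genes fell in 17 of 18 cases (17 adjusted over the list alone; camera adjusted p = 3.9e-21, adjusted p = 0.053 with an estimated correlation). Among them were Fads2 (-6.47 ± 0.37), Fads1 (-6.19 ± 0.34), Pklr (-6.04 ± 0.33) and Scd (-6.60 ± 0.42). The cholesterol list had 14 of 17 members down and 2 up (2 rose and 15 fell adjusted over the list alone; camera adjusted p = 6.7e-12, adjusted p = 0.16 with an estimated correlation). Lowest were Nsdhl (-3.45 ± 0.22) and Tm7sf2 (-3.35 ± 0.22), enzymes of sterol synthesis. In the fatty acid oxidation and PPARα target list 12 of 28 members fell and 1 rose (2 rose and 14 fell adjusted over the list alone; camera adjusted p = 1.5e-05, adjusted p = 0.43 with an estimated correlation). The falls included Fabp1 (-5.70 ± 0.49), the liver fatty acid binding protein, Hadh (-3.23 ± 0.36), a dehydrogenase of fatty acid oxidation, and Angptl4 (-2.99 ± 0.36), an inhibitor of lipoprotein lipase, while Cpt1a (1.88 ± 0.30) was the member that rose. Bdh1 (-6.07 ± 0.19) fell further than at phase 2. Genes of the urea cycle rose in 6 of 8 cases and 1 fell (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00017, adjusted p = 0.31 with an estimated correlation). Those that rose included Asl (2.50 ± 0.13), argininosuccinate lyase, Arg1 (1.61 ± 0.11), arginase, and Slc25a15 (1.92 ± 0.13), the mitochondrial ornithine carrier, and those that fell included Otc (-3.09 ± 0.69), ornithine transcarbamylase. Among gluconeogenic genes, 8 of 17 rose and 6 fell (camera adjusted p = 0.89). Pck1 (1.42 ± 0.35) and G6pc1 (1.19 ± 0.29), the enzymes at the start and the end of the pathway, rose with Got1 (2.81 ± 0.22), an aspartate aminotransferase, while Gk (-2.32 ± 0.21), glycerol kinase, fell.

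Antioxidant genes went both ways: 6 of 34 rose and 8 fell (7 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.32). Cat (-3.03 ± 0.46), Prdx4 (-1.41 ± 0.26), Gpx1 (-1.27 ± 0.15) and Sod1 (-0.68 ± 0.14) fell, and Hmox1 (2.62 ± 0.41) and Gpx3 (2.19 ± 0.31), the plasma glutathione peroxidase, rose. Sod2 (0.03 ± 0.24), the mitochondrial superoxide dismutase, and Gsr (-0.12 ± 0.17) were not called. Glutathione S-transferases fell in 5 of 14 cases and 1 rose (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.56 with an estimated correlation). Among them were Gstt1 (-2.28 ± 0.15) and Mgst1 (-1.47 ± 0.13). After quantile normalization the adjusted p of this list was 0.068. Oxidases that make hydrogen peroxide fell in 5 of 17 cases and rose in 2 (2 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.57 with an estimated correlation). Examples were Hao1 (-5.19 ± 0.63) and Hao2 (-4.19 ± 0.23), the peroxisomal hydroxyacid oxidases, and Nox4 (-3.49 ± 0.43), an NADPH oxidase. The oxidative phosphorylation list rose, with 18 of 42 members up (20 adjusted over the list alone; camera adjusted p = 9.1e-05, adjusted p = 0.57 with an estimated correlation). Among them were Uqcrfs1 (1.24 ± 0.28) and Cox4i1 (1.02 ± 0.24).

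Glucocorticoid-responsive genes rose in 12 of 16 cases and fell in 2 (13 rose and 2 fell adjusted over the list alone; camera adjusted p = 1.6e-06, adjusted p = 0.2 with an estimated correlation). After Igfbp1, the list was led by Ddit4 (4.37 ± 0.18), an inhibitor of mTORC1, Dusp1 (2.26 ± 0.28), a phosphatase of MAP kinases, and Per1 (2.25 ± 0.21), a clock gene. Ribosome biogenesis genes rose in 18 of 21 cases and 1 fell (19 rose and 1 fell adjusted over the list alone; camera adjusted p = 6.7e-12, adjusted p = 0.2 with an estimated correlation). Among them were Myc (3.57 ± 0.32), a transcription factor that drives ribosome synthesis, Wdr43 (2.65 ± 0.20) and Polr1c (2.59 ± 0.22), a subunit of RNA polymerases I and III. Chaperones and other genes of the endoplasmic reticulum fell in 14 of 22 cases and rose in 4 (5 rose and 15 fell adjusted over the list alone; camera adjusted p = 7.0e-05, adjusted p = 0.45 with an estimated correlation). The members that fell included Hyou1 (-2.34 ± 0.19) and Pdia6 (-2.04 ± 0.14), which fold proteins, and those that rose included Atf3 (3.16 ± 0.22) and Ppp1r15a (2.28 ± 0.17), genes of the stress response itself. Plasma proteins made by hepatocytes fell in 11 of 21 cases (15 adjusted over the list alone; camera adjusted p = 1.6e-06, adjusted p = 0.56 with an estimated correlation). Among them were Afm (-3.71 ± 0.48), afamin, C9 (-2.70 ± 0.35), a complement component, and Hrg (-2.00 ± 0.52), histidine-rich glycoprotein. Alb (-0.19 ± 0.08), albumin, was not called. The change of Hrg was -1.29 without P3 3. Clock genes rose in 10 of 15 cases and 1 fell (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.57 with an estimated correlation). Those that rose included Nfil3 (1.73 ± 0.31) and Tef (1.39 ± 0.19), and those that fell included Npas2 (-1.62 ± 0.12). In the growth hormone axis Ghr (-3.27 ± 0.25), the receptor, Igfals (-4.58 ± 0.67), the acid-labile subunit that carries insulin-like growth factors, and Igf1 (-1.94 ± 0.42) fell (2 of 13 members rose and 5 fell; camera adjusted p = 0.32).

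In all, 2125 rows were higher and 1523 lower in P3 than in fed livers, 854 and 772 by at least 2-fold. Of all rows tested, 19.6% had no overlap between the 4 values of 1 group and the 4 of the other, against 2.86% by chance. Among the 3648 rows called, which were chosen on these same values, 3071 had none. Without fed 2 the counts were 1765 higher and 1784 lower. Camera called 21 of the 41 lists, 13 over the brighter rows alone, 12 over the brighter rows with the trend with gene length taken out as well, and 0 with an estimated correlation (5 at an unadjusted p below 0.05). Of the 35 splits of these 8 arrays into 4 and 4, 2 called as many.

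Between the 2 phases of fasting, many antioxidant and detoxifying genes were lower at phase 3 than at phase 2, while many glucocorticoid-responsive genes and genes of ribosome biogenesis were higher. None of the list calls of this comparison held with an estimated correlation. Among the largest falls were Car3 (-7.10 ± 0.19), Dhrs7l1 (-5.88 ± 0.68), Cyp2c11 (-5.74 ± 0.50) and Fabp1 (-5.47 ± 0.49), along with Gstp3 (-4.98 ± 0.24), a glutathione S-transferase, and Rgn (-4.90 ± 0.55), regucalcin, an enzyme of the ascorbate pathway. Gadd45b rose by 5.29 ± 0.17 log2 units (adjusted p = 4.6e-11), Ppargc1a by 4.10 ± 0.29 and Sik1, a kinase induced by cyclic AMP, by 4.00 ± 0.25.

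Antioxidant enzymes fell in 16 of 34 cases and rose in 5 (5 rose and 20 fell adjusted over the list alone; camera adjusted p = 4.3e-05, adjusted p = 0.55 with an estimated correlation). Cat (-2.65 ± 0.46), Prdx4 (-2.59 ± 0.26), Gpx1 (-1.83 ± 0.15) and Sod1 (-1.28 ± 0.14) fell, and Hmox1 (2.10 ± 0.41) and Txnrd1 (0.90 ± 0.15), cytosolic thioredoxin reductase, rose. Glutathione S-transferases fell in 7 of 14 cases and 1 rose (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.0001, adjusted p = 0.42 with an estimated correlation). Among them were Gstt1 (-2.08 ± 0.15) and Mgst2 (-2.01 ± 0.19). Drug-metabolizing cytochromes P450 fell in 10 of 18 cases and rose in 2 (2 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.00024, adjusted p = 0.55 with an estimated correlation). Among them were Cyp3a2 (-3.23 ± 0.53) and Cyp1a2 (-2.64 ± 0.50). Cyp7a1 (2.77 ± 0.40), the rate-limiting enzyme of bile acid synthesis, rose. Fold changes of these livers followed gene length with a correlation of 0.21 across the brighter rows, the reverse of the trend at phase 2 against fed. With it taken out, the adjusted p was 0.00016 for the antioxidant list and 0.0027 for the glutathione S-transferases. Neither list held with an estimated correlation, as given above.

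Fatty acid oxidation and PPARα target genes fell in 19 of 28 cases and rose in 2 (3 rose and 19 fell adjusted over the list alone; camera adjusted p = 3.9e-08, adjusted p = 0.41 with an estimated correlation). Among them were Hadh (-3.12 ± 0.36) and Decr1 (-2.51 ± 0.27). Cpt1a (1.34 ± 0.30) rose. Urea cycle genes rose in 6 of 8 cases and 1 fell (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00072, adjusted p = 0.44 with an estimated correlation). Those that rose included Slc25a15 (1.72 ± 0.13) and Asl (1.44 ± 0.13), and those that fell included Otc (-3.17 ± 0.69). In the insulin signalling list 9 of 16 members rose and 1 fell (12 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00023, adjusted p = 0.5 with an estimated correlation). Among them were Irs2 (2.66 ± 0.27), an insulin receptor substrate, and Trib3 (1.28 ± 0.23), an inhibitor of AKT. Glucocorticoid-responsive genes rose in 11 of 16 cases and 1 fell (14 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.9e-06, adjusted p = 0.37 with an estimated correlation). Those that rose included Ddit4 (3.86 ± 0.18) and Dusp1 (2.41 ± 0.28), and those that fell included Hsd11b1 (-1.95 ± 0.19), which regenerates active glucocorticoid. Ribosome biogenesis genes rose in 18 of 21 cases (19 rose and 1 fell adjusted over the list alone; camera adjusted p = 6.0e-12, adjusted p = 0.37 with an estimated correlation). Among them were Myc (2.96 ± 0.32) and Nop58 (2.35 ± 0.22). Clock genes rose in 7 of 15 cases and 1 fell (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.46 with an estimated correlation). Among them were Bhlhe40 (2.35 ± 0.28) and Cry2 (2.01 ± 0.31). Plasma proteins fell in 16 of 21 cases (19 adjusted over the list alone; camera adjusted p = 2.6e-08, adjusted p = 0.46 with an estimated correlation). Among them were Afm (-2.97 ± 0.48), C9 (-2.76 ± 0.35) and Alb (-0.39 ± 0.08). Endoplasmic reticulum genes fell in 11 of 22 cases and rose in 4 (4 rose and 12 fell adjusted over the list alone; camera adjusted p = 0.0086, adjusted p = 0.58 with an estimated correlation). Among them was Pdia4 (-1.69 ± 0.22), a protein disulfide isomerase, while Atf3 (2.62 ± 0.22) rose. The lists of heat shock genes (camera adjusted p = 0.28) and of the amino acid response (camera adjusted p = 0.081) were not called.

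Together, 2543 rows were higher and 1611 lower in P3 than in P2, 1043 and 622 by at least 2-fold. Of all rows tested, 21.9% had no overlap between the 4 values of 1 group and the 4 of the other, against 2.86% by chance. Among the 4154 rows called, which were chosen on these same values, 3399 had none. With the spread of each array as a covariate the balance turned, with 1624 higher and 1760 lower. The upper quartile lay a mean of 1.65 log2 units above the median in P2 and 1.94 in P3. This covariate is therefore in part confounded with group. Camera called 14 lists and 0 with an estimated correlation (4 at an unadjusted p below 0.05). Of the 35 splits of these 8 arrays into 4 and 4, 12 called as many.

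After 2 days of re-feeding, many of the genes with large changes at phase 3 went back, though not all did so in full. Fads2, the delta-6 desaturase, rose by 7.50 ± 0.37 log2 units over P3 (adjusted p = 2.0e-09), Elovl6 by 7.34 ± 0.28, Car3 by 7.34 ± 0.19 and Scd by 7.22 ± 0.42. Igfbp1 fell by 7.91 ± 0.22 (adjusted p = 1.8e-12), Gadd45b fell by 6.27 ± 0.17 and Pck1 fell by 4.60 ± 0.35, and Cdkn1a (-4.67 ± 0.41), the cell cycle inhibitor p21, and Rdh16 (-4.95 ± 0.19) and Fst (-4.81 ± 0.18) fell too. Dhrs7l1, a short-chain dehydrogenase, lay 7.18 ± 0.68 below fed at phase 3 and was still 4.43 ± 0.68 below fed after re-feeding.

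Lipogenesis genes rose in 17 of 18 cases (18 adjusted over the list alone; camera adjusted p = 3.2e-25, adjusted p = 0.027 with an estimated correlation). Among them were Pnpla3 (6.98 ± 0.59), a lipid droplet acyltransferase and lipase, and Srebf1 (2.96 ± 0.21). This was the only list call of the 5 comparisons that held with an estimated correlation. Cholesterol genes rose in 15 of 17 cases and 1 fell (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.9e-15, adjusted p = 0.068 with an estimated correlation). The list was led by Acat2 (4.47 ± 0.28) and Nsdhl (3.95 ± 0.22). Fatty acid oxidation and PPARα target genes rose in 19 of 28 cases and 1 fell (19 rose and 2 fell adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.31 with an estimated correlation). Those that rose included Fabp1 (5.84 ± 0.49) and Hadh (3.12 ± 0.36), and those that fell included Cpt1a (-1.30 ± 0.30). The glycogen list rose in 6 of 7 members (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.41 with an estimated correlation). Among them were Ppp1r3b (4.42 ± 0.31) and Pygl (2.11 ± 0.24). Urea cycle genes fell in 4 of 8 cases and 1 rose (1 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.001, adjusted p = 0.37 with an estimated correlation). Those that fell included Asl (-2.01 ± 0.13), and those that rose included Otc (3.33 ± 0.69). G6pc1 (-2.86 ± 0.29) fell with Ppargc1a (-4.01 ± 0.29).

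Antioxidant enzymes rose in 15 of 34 cases and fell in 3 (19 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.00034, adjusted p = 0.59 with an estimated correlation). Cat (3.09 ± 0.46), Gpx1 (1.65 ± 0.15), Sod1 (1.15 ± 0.14) and Gclc (1.65 ± 0.26), the catalytic subunit of glutathione synthesis, rose, and Hmox1 (-2.35 ± 0.41) fell. Targets of the transcription factor NRF2 rose in 12 of 29 cases and fell in 3 (15 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.0054, adjusted p = 0.53 with an estimated correlation). Among them were Aldh1a1 (4.84 ± 0.44), an aldehyde dehydrogenase, and Me1 (3.44 ± 0.38), malic enzyme, which also supplies NADPH for lipogenesis. Glutathione S-transferases rose in 7 of 14 cases (9 adjusted over the list alone; camera adjusted p = 0.00046, adjusted p = 0.37 with an estimated correlation). Among them were Gstt1 (2.90 ± 0.15) and Mgst2 (1.98 ± 0.19). Peroxide-producing oxidases rose in 7 of 17 cases and 1 fell (7 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0054, adjusted p = 0.59 with an estimated correlation). Among them were Hao1 (5.14 ± 0.63) and Dao (3.82 ± 0.37), D-amino acid oxidase. Endoplasmic reticulum genes rose in 13 of 22 cases and fell in 4 (14 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.00017, adjusted p = 0.42 with an estimated correlation). Those that rose included Pdia6 (2.36 ± 0.14), and those that fell included Atf3 (-2.64 ± 0.22). Ribosome biogenesis genes fell in 16 of 21 cases (17 adjusted over the list alone; camera adjusted p = 2.7e-09, adjusted p = 0.31 with an estimated correlation). The list was led by Myc (-3.21 ± 0.32). Glucocorticoid-responsive genes fell in 10 of 16 cases and rose in 2 (2 rose and 13 fell adjusted over the list alone; camera adjusted p = 1.4e-07, adjusted p = 0.16 with an estimated correlation). Among them was Ddit4 (-4.13 ± 0.18). Plasma proteins rose in 11 of 21 cases (14 adjusted over the list alone; camera adjusted p = 8.2e-06, adjusted p = 0.56 with an estimated correlation). Among them was Afm (3.20 ± 0.48).

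Rows higher in P3r2 than in P3 numbered 1975 and rows lower 1498, 951 and 522 of them by at least 2-fold. Of all rows tested, 22.8% had no overlap between the 4 values of 1 group and the 4 of the other, against 2.86% by chance. Among the 3473 rows called, which were chosen on these same values, 3185 had none. The balance turned after quantile normalization (1894 higher and 2024 lower) and with the spread of each array as a covariate (2139 higher and 2165 lower). Camera called 15 lists. Of the 35 splits of these 8 arrays into 4 and 4, 6 called as many.

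Compared with livers that had never been fasted, re-fed livers differed in single clock genes and in genes of fat synthesis. Pnpla3 was higher by 5.07 ± 0.59 log2 units (adjusted p = 0.00037), Dbp, a clock output transcription factor, by 3.56 ± 0.28 (adjusted p = 7.2e-06) and Elovl6 by 2.91 ± 0.28. Pck1 fell by 3.18 ± 0.35 (adjusted p = 0.00024) and Bmal1, a core clock activator, fell by 2.80 ± 0.36. The largest differences also held Dhrs7l1 (-4.43 ± 0.68), Slc6a6 (-3.41 ± 0.32), the taurine transporter, Hbb-b1 (-2.63 ± 0.49), a haemoglobin chain of red cells, Fabp2 (2.75 ± 0.19), the intestinal-type fatty acid binding protein, and Hsd17b2 (2.55 ± 0.20), which inactivates sex steroids.

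Lipogenesis genes rose over fed in 7 of 18 cases (10 adjusted over the list alone; camera adjusted p = 1.4e-07, adjusted p = 0.36 with an estimated correlation). Among them was Me1 (2.01 ± 0.38). Cholesterol genes rose over fed in 4 of 17 cases (8 adjusted over the list alone; camera adjusted p = 5.8e-06, adjusted p = 0.36 with an estimated correlation). Examples were Acat2 (1.72 ± 0.28) and Mvd (1.28 ± 0.16), mevalonate diphosphate decarboxylase. In the gluconeogenesis list 2 of 17 members rose and 3 fell, Pck1, G6pc1 (-1.67 ± 0.29) and Gk (-1.35 ± 0.21) (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.94). Pck2 (0.53 ± 0.12), the mitochondrial form of Pck1, rose, with an adjusted p of up to 0.078 with single arrays left out (without P3r2 4). Igfbp1 fell by 1.93 ± 0.22. Of 15 clock genes, 6 rose and 2 fell (6 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.17), with Per3 (2.29 ± 0.24) and Per2 (1.69 ± 0.31) up. The oxidative phosphorylation list rose, with 9 of 42 members called (35 adjusted over the list alone; camera adjusted p = 5.5e-15, adjusted p = 0.36 with an estimated correlation). Among them was Ndufv2 (0.83 ± 0.13) of complex I. The citric acid cycle list rose too (5 of 19; 9 adjusted over the list alone; camera adjusted p = 7.6e-08, adjusted p = 0.24 with an estimated correlation). Examples were Pdhb (0.66 ± 0.11) and Mdh2 (0.57 ± 0.08). The proteasome list rose in 5 of 28 cases (20 adjusted over the list alone; camera adjusted p = 1.7e-10, adjusted p = 0.36 with an estimated correlation). Among them was Psmc5 (0.80 ± 0.15), for which fed 2 lay below the other fed arrays (6.39 against 7.07 to 7.11). The ribosome biogenesis list rose in 3 of 21 cases (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.0e-05, adjusted p = 0.46 with an estimated correlation). Among them was Rrs1 (1.29 ± 0.21). Antioxidant enzymes rose in 4 of 34 cases (14 adjusted over the list alone; camera adjusted p = 1.7e-06, adjusted p = 0.46 with an estimated correlation), while Cat (0.05 ± 0.46), Gpx1 (0.38 ± 0.15), Sod1 (0.47 ± 0.14) and Hmox1 (0.27 ± 0.41) were not called. Values spread wider in P3r2 than in fed, with upper quartiles a mean of 2.03 and 1.85 log2 units above the median. With the spread as a covariate the lean of rows to higher values was lost (330 higher and 351 lower). The list calls of this comparison under that setting are not given here. Asns (1.76 ± 0.22), asparagine synthetase, Arg1 (0.67 ± 0.11), Por (2.00 ± 0.29), the reductase that feeds cytochromes P450, and Cyp1a1 (1.75 ± 0.28) rose, and Hao2 (-1.25 ± 0.23) and Kynu (-1.41 ± 0.28), kynureninase, fell.

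Fewer rows were called here than in the other comparisons: 417 higher and 97 lower in P3r2 than in fed, 106 and 62 by at least 2-fold, so that 81.1% were higher, and after quantile normalization 53.3% were. Of all rows tested, 12.5% had no overlap between the 4 values of 1 group and the 4 of the other, against 2.86% by chance. Among the 514 rows called, which were chosen on these same values, 507 had none. Single arrays moved these counts: the higher count was 215 without fed 2 and 193, 206, 179 and 245 without P3r2 1, 2, 3 and 4, and the lower count was 56, 63, 63 and 57 without these 4. The lower count was also 179 without the 3 arrays of narrow spread and 351 with the spread as a covariate, where the higher count was 330. Camera called 17 lists and 0 with an estimated correlation (4 at an unadjusted p below 0.05). Of the 35 splits of these 8 arrays into 4 and 4, 1 called as many.

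**Figure D2:**
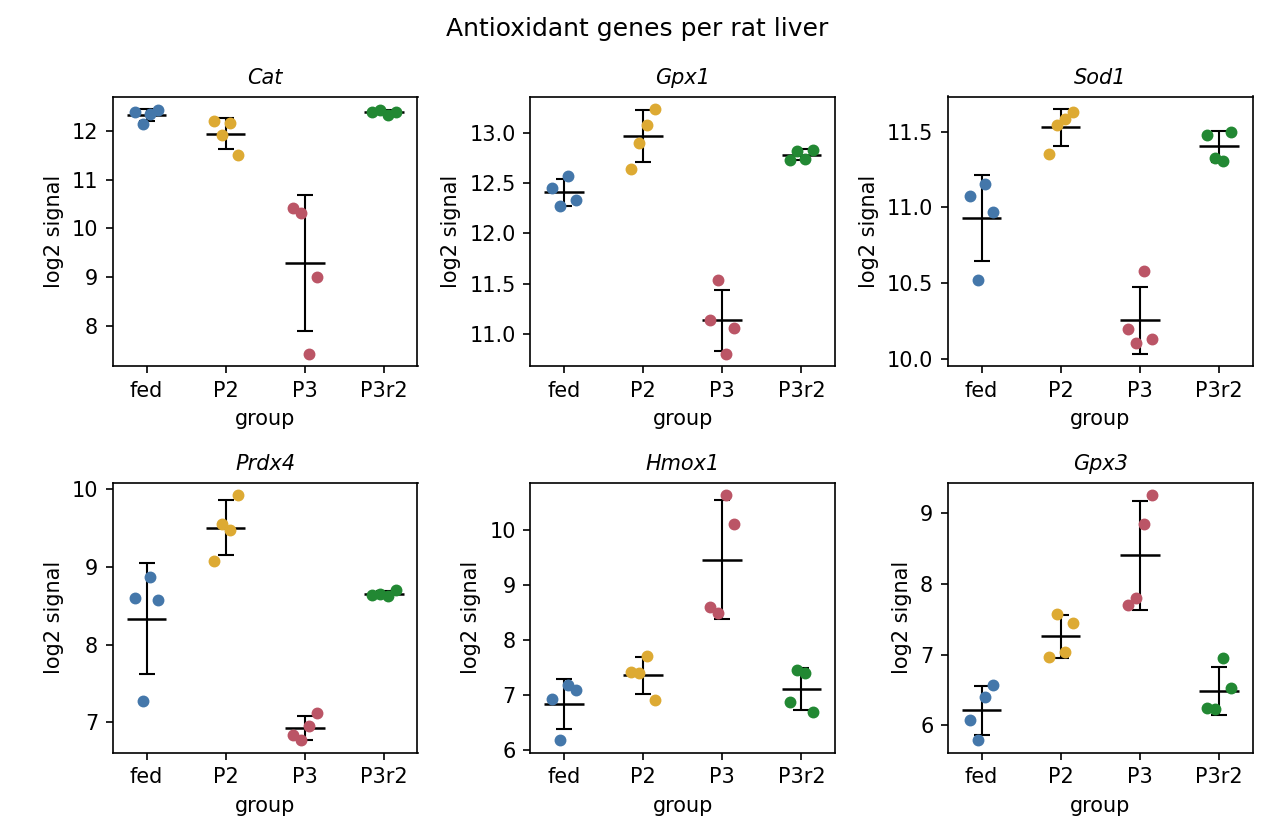
Log2 signal of 6 antioxidant genes in each of the 16 rat livers, by group. Points are arrays, horizontal lines group means and bars the standard deviation (n = 4). The group means of Cat, Gpx1, Sod1 and Prdx4 are lowest at phase 3, where those of Hmox1 and Gpx3 are highest.

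Many of the genes called in both phases of fasting moved the same way. Srebf1 fell by 2.13 log2 units at phase 2 and fell by 2.96 at phase 3, Ccnd1 fell by 2.38 and fell by 3.14, and Igfbp2 rose by 2.60 and 3.34. In all, 898 rows were called in the same direction in P2 and P3 against fed, 384 higher and 514 lower, 37.4% of those called at phase 2. Independent lists of these sizes would share 130 and 100, and 100 simulations of unchanged groups against the same fed arrays shared at most 496, with a median of 0 (limma, 199 at unadjusted p values below 0.05). With the fed arrays split 2 against 2, so that the comparisons shared none, the overlap was 284 to 482, where independent lists would share 34 to 118. The covariance of the log2 fold changes across rows was 0.131, against a simulated median of 0.0242 (range -0.0145 to 0.0864). In the splits it was 0.0928 to 0.12. The correlation was 0.43, against a simulated median of 0.54 (range -0.59 to 0.86). Without fed 4, 591 rows were shared.

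A smaller set moved one way at phase 2 and the other way at phase 3. Acsm5, a medium-chain acyl-CoA synthetase (2.30 ± 0.55 and -1.87 ± 0.55), Prdx4, the peroxiredoxin of the endoplasmic reticulum (1.18 ± 0.26 and -1.41 ± 0.26) and Sod1, the cytosolic superoxide dismutase (0.60 ± 0.14 and -0.68 ± 0.14) were higher than fed at phase 2 and lower at phase 3, and Bhlhe40, a repressor of the clock (-1.34 ± 0.28 and 1.01 ± 0.28) was lower and then higher. The phase 3 values of Acsm5 and Bhlhe40 fall outside the rule for named genes and were chosen after they were seen. There were 108 such rows with the difference between P3 and P2 also called, 44 higher then lower and 64 lower then higher. Counted as steps, 903 rows changed in 1 direction from fed to P2 and in the other from P2 to P3 (451 up first and 452 down first). Independent lists would give 266 and the simulations at most 14 (limma, a median of 92.5 and at most 1518 at unadjusted p values below 0.05). Splits of the P2 arrays gave 81 to 499, where independent lists would give 35 to 205. The covariance was -0.0758, against a simulated median of -0.0199 (range -0.0626 to 0.00698). In the splits it was -0.0577 to -0.0315. The correlation was -0.26, against a simulated median of -0.51 (range -0.89 to 0.36). The count was 547 without fed 1, 490 without fed 4, 540 without P2 2, 372 without P2 4, 1371 without P3 3 and 553 with the spread of each array as a covariate.

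Re-feeding brought most of the changes of phase 3 back: 2471 of the 3648 rows called in P3 against fed (67.7%) were called in the other direction in P3r2 against P3. The share was 59.4% for rows higher at phase 3, 79.3% for rows lower at phase 3, and 85.1% for rows changed at least 2-fold. Of the rows called back, 2322 (94.0%) were no longer called against fed, as for Car3 (-0.60 ± 0.19 against fed), Cat (0.05 ± 0.46) and Hmox1 (0.27 ± 0.41). A row not called may still differ, since only 20% of simulated 1.5-fold changes were called in P3r2 against fed. Of the other rows called back, 75 still lay on the side of phase 3, among them Slc34a2 (-2.36 ± 0.46) and Por (2.00 ± 0.29). The remaining 74 lay past fed on the other side, among them Pnpla3 (5.07 ± 0.59), Pck1 (-3.18 ± 0.35) and Cdkn1a (-2.27 ± 0.41). A further 162 rows were not called back and still differed from fed. Among them, Dbp and Slc6a6 moved further from fed on re-feeding. Dbp went from 0.97 against fed at phase 3 to 3.56 ± 0.28, and Slc6a6 from -1.31 to -3.41 ± 0.32. Only 5 rows were called in the same direction in both steps. The other 1015 rows not called back were not called in P3r2 against fed. Independent lists would give 328 rows called back, and the simulations with unchanged groups at most 0 (limma, a median of 109 at unadjusted p values below 0.05). Splits of the P3 arrays gave 1517 to 1689, where independent lists would give 160 to 204. The covariance of the fold changes was -0.395, against a simulated median of -0.0227 (range -0.0467 to 0.00506). In the splits it was -0.376 to -0.351. The correlation was -0.88, against a simulated median of -0.53 (range -0.89 to 0.25).

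**Figure D3:**
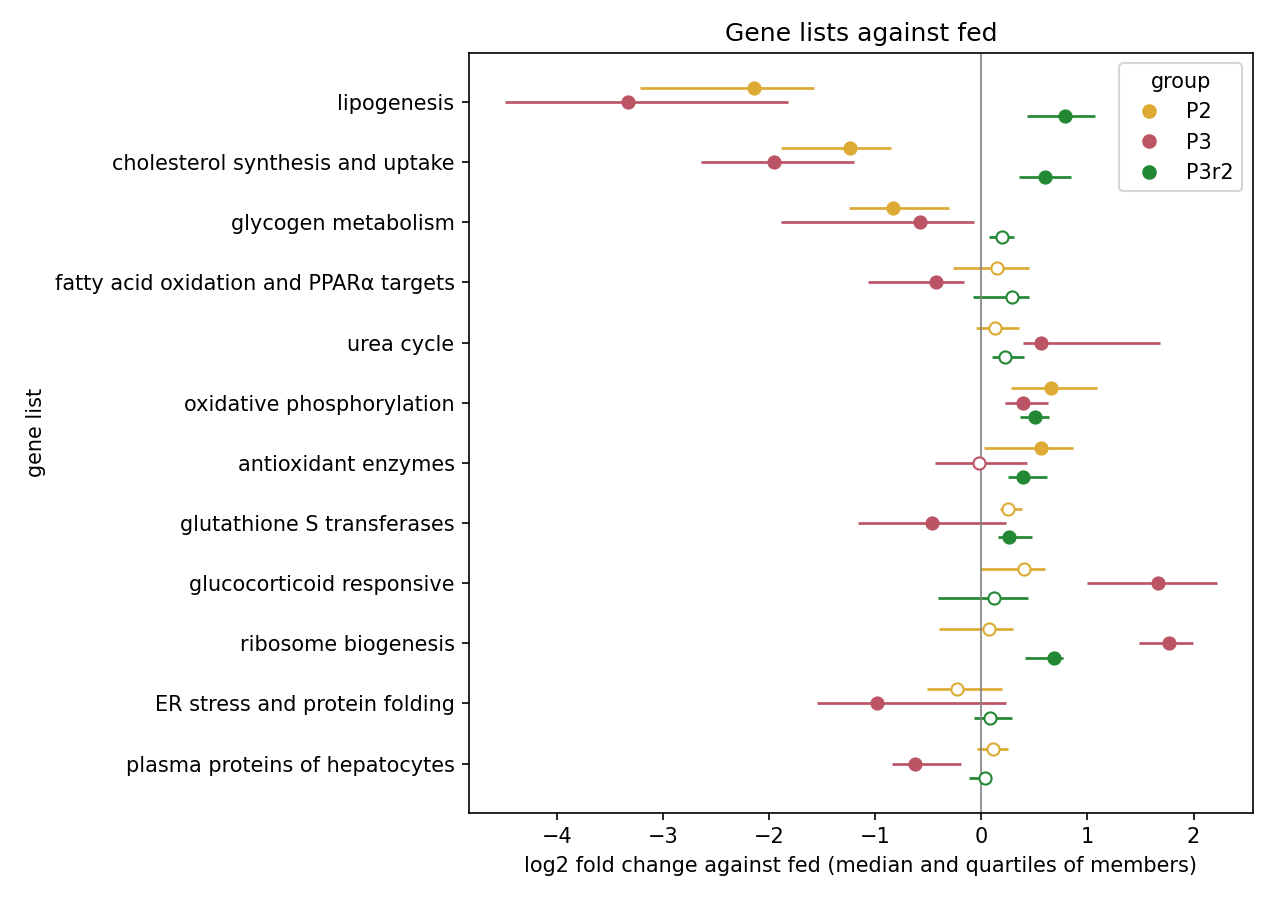
Median log2 fold change against fed of the measured members of 12 gene lists, at phase 2, at phase 3 and after re-feeding, with bars from the lower to the upper quartile of the members. Filled points are lists called by camera with the preset correlation and open points lists not called. Lipogenesis and cholesterol synthesis lie below 0 in both phases and above 0 after re-feeding.

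Some markers of stellate cells and fibroblasts fell at phase 2, and several other marker lists were not called in any comparison. Of 18 measured markers of Kupffer cells and macrophages, 2 rose at phase 2 and 2 at phase 3, and the list was not called in any comparison (lowest camera adjusted p = 0.06). The same held for the lists of hepatocytes (lowest camera adjusted p = 0.31), where at phase 3 3 of 9 markers rose and 3 fell, cholangiocytes (lowest camera adjusted p = 0.43), adipocytes (lowest camera adjusted p = 0.17) and exocrine pancreas (lowest camera adjusted p = 0.14). Stellate cell and fibroblast markers fell at phase 2 in 7 of 17 cases and 1 rose (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.0033, adjusted p = 0.89 with an estimated correlation). Examples were Pdgfrb (-1.54 ± 0.23) and Lrat (-1.06 ± 0.22). With the trend with gene length taken out over the brighter rows the median of this list was -0.34, against -0.58 over all rows with the trend left in. After re-feeding the stellate list was lower than in fed livers with 1 member called (camera adjusted p = 0.00035, adjusted p = 0.53 with an estimated correlation). Lymphocyte markers were lower at phase 3 than at phase 2, with 3 of 14 called (4 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.46 with an estimated correlation), and without the 3 arrays of narrow spread the adjusted p was 0.072. Endothelial markers were lower after re-feeding than at phase 3, with 3 of 11 called (1 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.035, adjusted p = 0.56 with an estimated correlation). Neutrophil markers lay lower in re-fed than in fed livers by a median of -0.16 log2 units (camera adjusted p = 0.0023, adjusted p = 0.36 with an estimated correlation), with no single marker called by limma (1 of 10 at an unadjusted p below 0.05). With 4 measured markers the red cell list was not tested as a list, and 1 of them, Hbb-b1, fell in re-fed against fed livers (-2.63 ± 0.49) and in P3 against fed (-2.07 ± 0.49). Hba-a3, another haemoglobin chain, was also called lower in these 2 comparisons (-2.35 and -1.65). It falls outside the rule for named genes and was chosen after its values were seen.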

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

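The tests of gene length in single arrays and on lists, of the share of hepatocytes and of the clock were chosen only after the results were seen. That of the share of hepatocytes replaced 2 earlier ones on the same marker lists, of which the number with a median below 0 (4 of 5) argued against a lower share and the number with both quartiles below 0 (1 of 5) left it open. Leaving out the 3 arrays of narrow spread was added after their spread was seen, but what it would show was written down before that test was run.

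The effects of the 2 phases of fasting against fed livers differed by limma's test of the difference itself in 108 rows that were called in opposite directions. Among the genes named in the text, the P3 minus P2 difference was -4.17 for Acsm5 (P2 2.30 and P3 -1.87 against fed), 2.77 for Cyp7a1 (P2 -1.38 and P3 1.39 against fed), -2.59 for Prdx4 (P2 1.18 and P3 -1.41 against fed), 2.35 for Bhlhe40 (P2 -1.34 and P3 1.01 against fed). It was -2.01 for Mgst2 (P2 0.69 and P3 -1.32), -1.95 for Hsd11b1 (P2 0.60 and P3 -1.35), -1.83 for Gpx1 (P2 0.56 and P3 -1.27) and -1.28 for Sod1 (P2 0.60 and P3 -0.68), all in log2 units. The phase 2 calls of Cyp7a1, Mgst2 and Gpx1 were lost with single arrays left out, with adjusted p of up to 0.12, 0.088 and 0.086 (without P2 4 in each case).

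Fold changes of P2 against fed followed gene length, short genes being higher and long genes lower. The 3 arrays of narrow spread do not account for it, since the Spearman correlation across genes was -0.29 with all arrays and -0.30 without them. Whether a length trend that differs between single arrays accounts for it cannot be told. Of the 16 arrays, 4 deviated from their own group along gene length with a correlation beyond 0.2 in size, a bound set after the data were seen. These were fed 4, P3 1, P3 3 and P3r2 4, none of them a P2 array, and 9 arrays passed the bound over the brighter rows. Deviations from a group's own mean do not by themselves give a difference between group means. They show how far single arrays scatter along length, and so how far means of 4 arrays may differ. Against the mean of all arrays, the P2 arrays had correlations of -0.16, -0.25, -0.16 and -0.27 with length, and the fed arrays -0.01 to 0.29. P3 3 had -0.15 and P3r2 4 had -0.10, and the other P3 and P3r2 arrays had 0.05 to 0.20. With the trend taken out over the brighter rows, the oxidative phosphorylation list had an adjusted p of 4.5e-09 with the preset correlation (adjusted p = 0.58 with an estimated correlation and the trend left in), which argues against the trend as its whole cause. For the proteasome list the camera adjusted p was then 0.043 and the median 0.28, against 0.40 over all rows with the trend left in. For the stellate cell list the adjusted p was 0.047 and the median -0.34, against -0.58 likewise. For these lists the trend and the state of the liver cannot be told apart, because the p values stayed close to the threshold. Their medians before and after also come from different sets of rows. With an estimated correlation and the trend left in, the adjusted p was 0.89 for each of them. A true effect of fasting on long genes was not tested.

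The plasma protein list fell in P3 against fed (median -0.62; camera adjusted p = 1.6e-06, adjusted p = 0.56 with an estimated correlation). A lower share of hepatocytes would raise the markers of all other liver cells alike, but 3 pairs of the 5 lists of such markers moved apart by more than their quartiles, endothelial markers (median 0.34) lying above those of stellate cells (-0.29), cholangiocytes (-0.04) and lymphocytes (-0.16). All 3 pairs hold the endothelial list, so a change in endothelial cells alone could give this result, and it does not decide about a lower share. The hepatocyte markers went both ways, with 3 of 9 up and 3 down. A lower share and a change in endothelial cells both stay open. Without the 3 arrays of narrow spread the adjusted p of the list, with the preset correlation, was 4.2e-06, and with the length trend taken out it was 6.8e-05. The authors' summarisation of bright probe sets could not be tested, and a lower output of plasma protein mRNA at phase 3 may be a biological explanation, which stays open.

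Clock genes differed between re-fed and fed livers. Usp2 (2.23 ± 0.34, adjusted p = 0.0025) and Wee1 (1.43 ± 0.34, adjusted p = 0.035), clock-driven genes outside the list that peak with Per and Dbp, were both called higher in P3r2, so 2 of the 2 genes went with another phase of the clock at sampling. Length does not account for it, since 8 of the 8 called clock genes were still called in the same direction with the length trend taken out. Wee1 was already higher at phase 3 (1.87, adjusted p = 0.00077) and was not called in P3r2 against P3 (-0.44, adjusted p = 0.47), and the clock list was called higher in P3 against fed (camera adjusted p = 0.012, adjusted p = 0.57 with an estimated correlation), so a lasting effect of the fast may account for a part. An hour of sampling, the meals of re-feeding and the fast all stay open, since times are not given in the sources used here.

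In 38 of 560 groups of 4 arrays (6.79%) over the 140 genes named, 1 array lay far from the other 3 by Dixon's criterion, where chance flags about 1 in 20 groups, and 13 of these values lay in fed 2 and 6 in P3 3. fed 1 held Cyp1a1 at 4.13 against 3.85 to 3.86. fed 2 held Alb at 13.15 against 13.33 to 13.37, Ctsl at 9.92 against 10.63 to 10.75, Cyp2c11 at 11.88 against 12.34 to 12.40, Fabp1 at 11.65 against 11.98 to 12.03, Lrat at 7.53 against 8.42 to 8.59, Mgst1 at 12.52 against 12.70 to 12.72, Nox4 at 5.21 against 7.10 to 7.46, Nsdhl at 10.92 against 11.10 to 11.13, Otc at 9.86 against 10.80 to 10.87, Psmc5 at 6.39 against 7.07 to 7.11, Psmd12 at 8.13 against 8.89 to 8.99, Rgn at 10.87 against 11.56 to 11.69 and Sod2 at 7.89 against 9.17 to 9.33. fed 4 held Scd at 11.65 against 12.31 to 12.36. P2 2 held Myc at 6.30 against 5.29 to 5.42. P2 3 held Mvd at 5.66 against 5.86 to 5.90, Plin2 at 9.56 against 8.64 to 8.80 and Slc34a2 at 7.67 against 5.02 to 5.29. P2 4 held Fst at 4.02 against 3.82 to 3.85, Igf1 at 10.90 against 11.33 to 11.41 and Pck1 at 11.10 against 11.86 to 11.91. P3 1 held Paqr9 at 6.51 against 5.34 to 5.40. P3 2 held Gk at 7.70 against 7.98 to 8.03. P3 3 held Alb at 12.98 against 13.15 to 13.18, Bcl2l11 at 6.30 against 7.85 to 7.90, Cyp7a1 at 10.63 against 12.49 to 12.76, Eci1 at 8.17 against 7.25 to 7.33, Per2 at 5.46 against 6.10 to 6.21 and Prdx5 at 10.24 against 9.72 to 9.78. P3r2 1 held Cdkn1a at 4.68 against 5.95 to 6.08. P3r2 2 held Hao2 at 10.35 against 9.78 to 9.87 and Psmb8 at 9.70 against 9.38 to 9.43. P3r2 3 held Aldh1a1 at 9.92 against 10.44 to 10.45 and Me1 at 9.85 against 10.73 to 10.82. P3r2 4 held Mgst1 at 12.94 against 12.74 to 12.77, Mgst2 at 11.18 against 10.78 to 10.81 and Psmb1 at 9.31 against 8.98 to 9.03, all log2 signals.

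The 533 rows without gene names, tested apart from the others, held 176 called rows in P2 against fed and 70 in P3 against fed. They held 128 in P3 against P2, 72 in P3r2 against P3 and 3 in P3r2 against fed. Of the 18885 rows tested, 2400, 3648, 4154, 3473 and 514 were called in the same order. Set against these counts, the rows without gene names were called clearly more often only in P2 against fed. They were called about as often in P3 against P2 and less often in the other comparisons. Their median log2 fold change in P2 against fed was 0.20, and what they measure is not given in the sources used here.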

How the results depend on the processing

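Leaving out the 3 arrays of narrow spread, the spread of each array as a covariate, both corrections for gene length and the rows without gene names were chosen after the data were seen, and the other alternatives before. No called value of a named gene turned its direction under the 26 alternatives run on named genes, of which the length correction over the brighter rows covered 623 of these values. Other alternatives, such as the fit of 2 groups alone, were run on counts only. Of the called values, 586 to 627 of 645 were still called with single arrays left out. With single arrays left out, the count of rows higher and lower was 608 to 1387 and 592 to 1626 in P2 against fed and 1669 to 2229 and 1236 to 1784 in P3 against fed. It was 2026 to 2895 and 1294 to 1767 in P3 against P2, 1643 to 2137 and 1145 to 1626 in P3r2 against P3, and 179 to 513 and 56 to 114 in P3r2 against fed. The lists called then numbered 8 to 13, 18 to 23, 13 to 16, 14 to 18 and 14 to 19 in the same order. Rows changed the same way in both phases numbered 591 to 910, rows called back after re-feeding 2025 to 2677 and rows turning between the phases 372 to 1371. At an adjusted p below 0.01, P2 against fed had 381 higher and 438 lower rows, P3 had 894 lower than P2. At that threshold P3r2 had 890 lower than P3 and 126 higher and 43 lower than fed, and the 3 overlaps held 393, 1625 and 219, since fewer rows pass a stricter threshold. Array weights gave 1894 lower rows in P2 against fed and 1146 higher and 321 lower in P3r2 against fed. A fit of the fed and P2 arrays alone gave 638 higher rows in P2. Quantile normalization gave 209 higher and 183 lower in P3r2 against fed. With the spread as a covariate, 769 rows were lower in P2 than fed, 1624 higher in P3 than P2, 351 lower in P3r2 than fed and 553 turned between the phases, and 15 lists were called in P2 against fed. Without the 3 narrow arrays, 179 rows were lower in P3r2 than fed and 14 lists were called in P2 against fed. With the length trend taken out over the brighter rows, 215 rows were lower in P3r2 than fed and 12 lists were called in P3 against fed, where the brighter rows alone gave 13. The cause of these differences was not tested. With an estimated correlation camera called 0, 0, 0, 1 and 0 lists in the 5 comparisons (2, 5, 4, 5 and 4 at an unadjusted p below 0.05). Splits of the shared arrays, which leave 2 arrays for each comparison, gave 415, 391, 284, 473, 482, 366 rows changed the same way in both phases. They gave 1663, 1517, 1540, 1571, 1519, 1689 called back after re-feeding and 128, 310, 81, 499, 362, 130 turning between the phases. The labels do not say whether the replicate numbers pair the animals, and the values showed little sign of it. In their deviations from the group means, 6 of 24 pairs of arrays with the same number correlated above 0.1, and 2 of 16 arrays correlated best with their own number. Weak correlations cannot exclude a pairing. With the replicate number as a block the counts were 955 higher and 1009 lower in P2 against fed and 2019 and 1404 in P3 against fed. The block gave 2442 and 1453 in P3 against P2, 1876 and 1396 in P3r2 against P3, and 341 and 83 in P3r2 against fed. With the block there were 10, 20, 15, 15 and 17 lists, overlaps of 793, 2335 and 703, and 614 of the called values of named genes still called. Signal over background limits what dim genes can show: over the brighter rows alone, the cell cycle list in P2 against fed had an adjusted p of 0.098.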

Other observations

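Single genes of several other lists were also called at phase 3. In the amino acid response list, 8 of 20 members rose at phase 3 and 4 fell (8 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.14), with Ddit4 (4.37 ± 0.18) and Trib3 (2.75 ± 0.23) up. Autophagy and lysosome genes rose in 10 of 30 cases at phase 3 and fell in 5 (10 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.15), among them Map1lc3b (2.55 ± 0.19), a protein of the autophagosome membrane, and Ctsl (1.96 ± 0.17), a lysosomal protease. Gabarapl1 (1.94 ± 0.17), of the same family as Map1lc3b, rose too. The proteasome list rose at phase 3 with 13 of 28 members up and 2 down (17 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.61 with an estimated correlation). Psmd12 (1.18 ± 0.16) was among those that rose, and Psmb8 (-2.39 ± 0.20) and Psmb9 (-2.18 ± 0.20), subunits of the immunoproteasome, were those that fell. Bile acid genes fell in 8 of 20 cases and rose in 3 (3 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.57 with an estimated correlation), with Slco1b2 (-3.98 ± 0.48) and Slc10a1 (-2.82 ± 0.62), uptake carriers of hepatocytes, down, and the adjusted p of this list was 0.061 after quantile normalization. In the list of apoptosis genes Bcl2l11 (2.91 ± 0.30), a pro-apoptotic BCL2 family member, and Cdkn1a (2.40 ± 0.41) rose and Xiap (-2.13 ± 0.23), a caspase inhibitor, fell. In all 6 of its 22 members rose and 2 fell, and the list was not called (camera adjusted p = 0.17).

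No test in this part was chosen after its result was seen. As a check on chance, the 8 arrays of each pair of groups were split into 4 and 4 in all 35 ways. The number of rows called was reached by 1 of the 35 splits, the real one, in each comparison: 2400 rows in P2 against fed with 1 as the highest other, 3648 in P3 against fed with 5. It was 4154 in P3 against P2 with 1, 3473 in P3r2 against P3 with 0, and 514 in P3r2 against fed with 1, so chance can be excluded for the counts of rows. The number of lists called with the preset correlation was reached by other splits too. In P2 against fed, 9 of the 35 splits called at least the real 9 lists, with 16 as the highest other. In P3 against fed 2 called at least 21 (highest other 21). In P3 against P2 12 called at least 14 (highest other 18), and in P3r2 against P3 6 called at least 15 (highest other 17). Some of these splits keep most arrays of a group together and so carry a part of the real difference. In P2 against fed all other splits that reached 9 lists were of this kind. In P3 against P2 and in P3r2 against P3, splits with 2 arrays of each group on each side also reached the real count. They called up to 17 and 15 lists, so there such counts arose with the group difference balanced out. In P2 and P3 against fed the splits cannot decide whether the number of lists arose by chance. Chance is not excluded for the number of lists in any of these 4 comparisons. In P3r2 against fed, 1 of the 35 splits, the real one, called at least 17 lists (highest other 15). By this count alone chance would be excluded there, but by a narrow margin, and 1 of 35 is the smallest share the check can give. Only this 1 of the 5 comparisons reached it for lists. Single arrays left out gave 14 to 19 lists, and camera with an estimated correlation called 0 (4 at an unadjusted p below 0.05). So chance is not firmly excluded for this number of lists either.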
